A study of Mus musculus with 6 samples.

How the data were processed

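RNA was sequenced from mouse bone marrow-derived dendritic cells with a stranded mRNA kit, per the labels' protocols. Bone marrow was cultured with 20 ng/mL GM-CSF, the medium was changed on day 3 and day 5, and cells were plated in wells. There were 3 libraries from cells given IFN-γ and 3 from cells given IFN-γ and 4-OI, grouped and numbered by their titles. The labels give no dose, duration, animal or batch. Replicate numbers are shared between groups without a statement that they pair samples.

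The authors deposited 1 table per sample with counts, TPM and FPKM for the same 36706 genes. The submitters' processing notes name HISAT2 and mm10; the counting program, its strand setting and the annotation release are not given in the sources used here. Counts were whole numbers per gene, per the file headers, and were used as deposited. The deposited TPM and FPKM values were recomputed from the counts and gene lengths and matched within a relative tolerance of 1e-06 for 100% of values, so they carry no further information and were not tested. Of 35208 genes with a match in the RefSeq table of GRCm38, 776 shared a start or an end with it, although 23385 had the same span in bases. Coordinates are therefore printed as the deposited tables give them, on an assembly that may differ from the mm10 the notes name. The same table was used for gene classes and older symbols (96.1% of symbols matched), and GENCODE transcripts of that assembly for GC content. No mitochondrial genes were among the rows.

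Libraries were compared with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr with its minimum count of 10, libraries scaled by TMM factors, and groups compared by the robust quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. CPM are TMM-scaled and are given as mean ± SD over 3 libraries; fold changes are those of the fit, with their SE. Total counts were 19656368 to 29244717 per library, at which 3 counts correspond to 0.103 to 0.153 CPM; this covers counting error only. No pair of libraries agreed within sampling noise: the lowest chi-square per gene between replicates was 4.35. Counts were simulated for the 14011 genes tested in the comparison of both groups, with 200 changed. The test recovered 45.5% of genes changed 1.5-fold, 77.3% of those changed 2-fold and 98.5% of those changed 4-fold. Of its calls, 8.23% were unchanged genes. In the data 6736 genes were called, and the adjusted threshold depends on how many genes change. These rates therefore do not carry over to the real comparison.

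The test, the gene lists, the markers of cell types and the rule for naming genes were fixed before the data were examined. Lists were tested with limma 3.58.1 camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 34 lists with at least 3 tested members; the erythroid list had 2 and was not tested. Camera with an estimated correlation, without the variance trend used in the other, and fry were run beside it. Adjusted over the list alone, the counts of members were the same for 28 lists; they differed for the type I interferon, integrated stress response (16 higher), LXR (5 higher), lysosome (23 higher), monocyte and neutrophil (10 lower) lists. A member of several lists counts in each. Genes named are the 10 largest rises and the 10 largest falls among genes past 0.05 with a group mean of at least 10 CPM and groups that did not overlap, without predicted genes and pseudogenes; of each gene list the 3 members with the smallest adjusted p, or 1 if none passed; and a set of 20 genes named in advance. Genes named to complete a small count of list members, and marker genes, were chosen after their values were seen. Results of some genes under these rules are not reported here. Of the listed symbols, Cxcl11, Mx1, Mx2, Ighm and Trbc2 are not analysed here.

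Each result was recomputed with RLE, upper quartile and no scaling factors, without the filter, with at least 1 CPM in 3 libraries, with limma-voom, with the replicate number as a block, without each library in turn and with protein-coding genes only; counts of genes and single genes also with DESeq2 1.42.0, and the count of changed genes at an adjusted p of 0.01. Where a setting did not keep or give a gene, it has no value there. Fits without IFN-γ replicate 1 and 4-OI replicate 3 together, and without the 2 genes resembling ribosomal RNA, were added after the data had been seen.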

Results

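Messenger RNA was measured by sequencing in mouse dendritic cells grown from wild-type bone marrow with GM-CSF, the cytokine that drives bone marrow precursors towards dendritic cells and macrophages in culture. All 6 libraries came from cells given interferon gamma (IFN-γ), and in 3 of them the cells also received 4-octyl itaconate (4-OI), a cell-permeable derivative of itaconate, the metabolite made by the enzyme that Acod1 encodes. The sample titles call the cells macrophages while the cell type label and the protocol call them dendritic cells, and dendritic cells is used here. The libraries held 22479177, 27510232 and 21710639 counts with IFN-γ and 19656368, 29244717 and 28218120 with IFN-γ and 4-OI. Both groups lay apart on the first principal component, which held 79.5% of the variance, and Spearman correlations of log2 CPM were 0.986 to 0.998 within groups and 0.941 to 0.961 between them. IFN-γ replicate 1 stood apart from replicates 2 and 3 on the second component. Reads of 2 genes resembling ribosomal RNA took 0.135%, 0.153% and 0.192% of counts with IFN-γ and 1.03%, 0.210% and 2.28% with 4-OI. No label says that the replicates came from separate cultures or animals, so p-values measure the spread between these libraries, which can be technical.

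The question was which genes 4-OI changed in cells given IFN-γ. All 29 tested targets of NRF2 rose, with Hmox1 11.0-fold higher, while 23 of 29 genes induced by IFN-γ, 23 of 27 stimulated by type I interferon and 23 of 26 of proliferation fell, with Gbp5 4.32-fold and Ccnb1 5.38-fold lower. As lists, the NRF2, IFN-γ, type I interferon and proliferation genes passed by camera with a preset correlation. With an estimated one they did not (camera adjusted p = 0.173 for the first 3 and 0.146 for proliferation). The test fry, which does not compare a list with other genes, called each of them in the same direction. Of 14011 genes tested with edgeR's quasi-likelihood test, 6736 passed a Benjamini-Hochberg adjusted p of 0.05, 3181 of them higher and 3555 lower with 4-OI. A change of at least 2-fold was found for 2447, of which 894 were higher and 1553 lower. With libraries scaled by total counts alone, 1719 genes were higher and 5452 lower, a share of higher calls of 24.0% against 47.2%, because that scaling moved the median log2 fold change of the tested genes to -0.27. The 10 most abundant genes took 7.37% to 8.59% of the counts with IFN-γ and 15.1% to 16.9% with 4-OI.

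The 29 targets of NRF2, the transcription factor that KEAP1 holds in check, rose with a median log2 fold change of 1.94 (camera adjusted p = 6.76e-18, and adjusted p = 0.173 with an estimated correlation). Hmox1, which encodes the heme-degrading enzyme heme oxygenase 1, went from 813 ± 113 to 8948 ± 219.9 CPM (SD, n = 3; log2 fold change 3.46 ± 0.14, SE; edgeR adjusted p = 2.31e-06). It lies on chromosome 8, 75820246 to 75827221, plus strand. Gclc, which encodes the catalytic subunit of the first enzyme of glutathione synthesis, went from 27.9 ± 2.62 to 356 ± 29.4 CPM, and Gclm, its modifier subunit, from 56.8 ± 6.66 to 539 ± 23.7 CPM. Srxn1, which encodes sulfiredoxin, was 15.7-fold higher, Nqo1, a quinone reductase, 6.77-fold, and Prdx1, a peroxiredoxin, 20.7-fold. Nfe2l2, the gene of NRF2, was 1.54-fold higher (edgeR adjusted p = 5.24e-04). Keap1 was 1.18-fold higher (edgeR adjusted p = 0.0360), a call lost under upper quartile factors, with the replicate block, with no filter on low counts and without any 1 of 4 single libraries, and its log2 fold change was -0.02 with total-count scaling. Acod1 was 2.54-fold higher, from 279 ± 5.67 to 708 ± 4.46 CPM (edgeR adjusted p = 8.42e-06).

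Chaperone genes of the heat shock factor HSF1 rose in 15 of 17 cases and none fell, with a median of 1.00 (camera adjusted p = 2.08e-08, and adjusted p = 0.173 with an estimated correlation). Hsph1 was 3.82-fold higher, from 47.7 ± 2.17 to 182 ± 7.35 CPM, and Hspa8 3.34-fold. Hspa1b was 5.16-fold higher, but it is nearly identical to Hspa1a, and reads that the pair may share were not measured. Of 31 lysosome and autophagy genes, 22 rose and 3 fell, with a median of 0.50 (camera adjusted p = 1.74e-05, and adjusted p = 0.251 with an estimated correlation). Gabarapl1, an autophagosome protein, was 3.33-fold higher, Atp6v0d2, a subunit of the proton pump, 2.37-fold and Gpnmb 2.23-fold. Uvrag and Mitf were among those that fell, with log2 fold changes of -0.80 and -0.36.

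**Figure D1:**
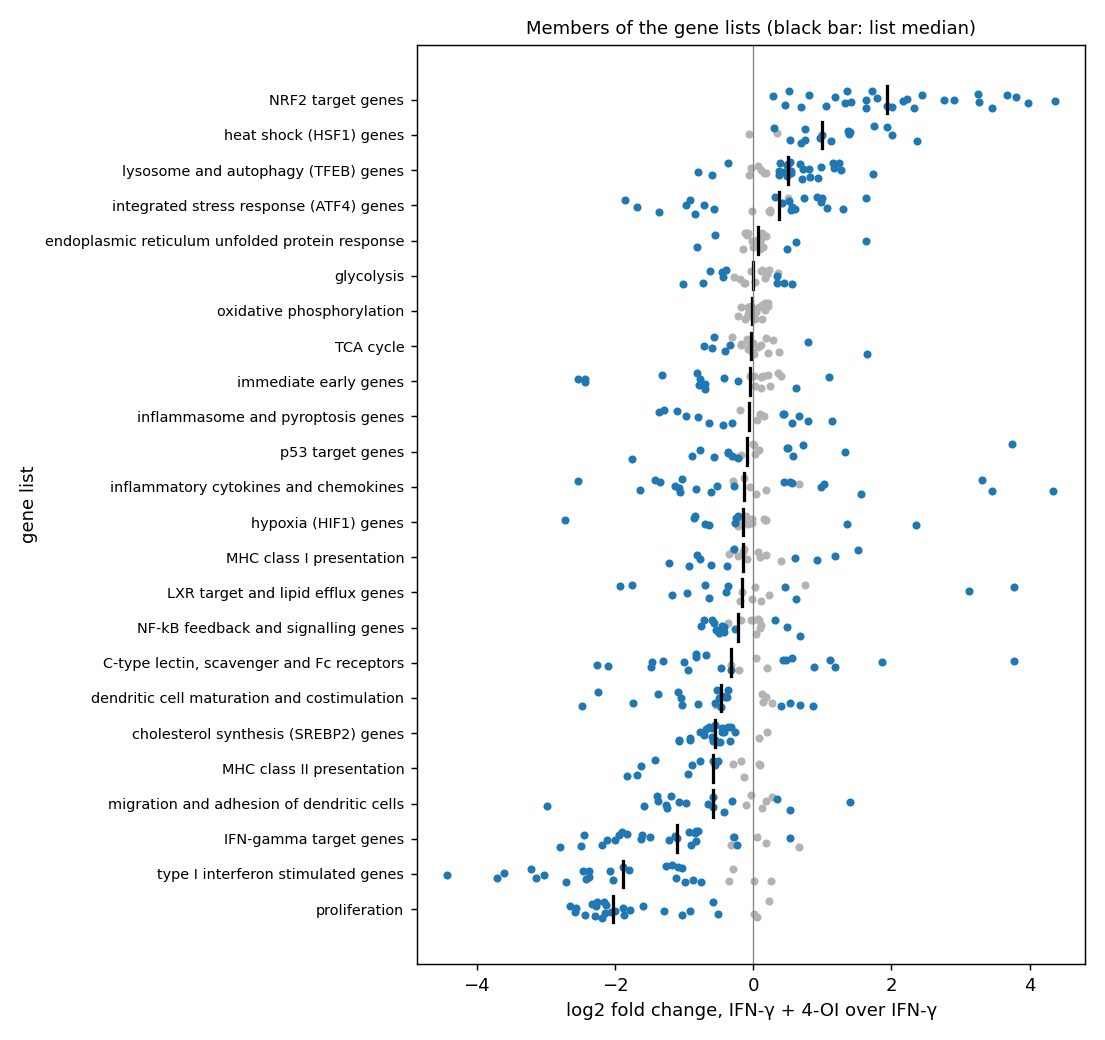
Log2 fold change (x axis, IFN-γ with 4-OI over IFN-γ) of each tested member of the 24 gene lists (y axis); blue points passed the edgeR adjusted p of 0.05, grey points did not, and black bars are list medians. NRF2 targets lie farthest right, with a median of 1.94, and proliferation genes farthest left, with a median of -2.03.

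Genes induced by IFN-γ fell in 23 of 29 cases, with a median of -1.10 (camera adjusted p = 1.35e-07, and adjusted p = 0.173 with an estimated correlation). Gbp5, which encodes a guanylate-binding protein, fell from 83.8 ± 4.32 to 19.4 ± 0.687 CPM (SD, n = 3; log2 fold change -2.11 ± 0.09, SE; edgeR adjusted p = 2.31e-06). It lies on chromosome 3, 142202695 to 142228105, plus strand. Gbp6, of the same family, fell 5.45-fold, Irf1 1.89-fold and Nos2, inducible nitric oxide synthase, 4.57-fold. Icam1 alone rose, with a log2 fold change of 0.54. Of the receptor chains, Ifngr1 had a log2 fold change of -0.25 (edgeR adjusted p = 0.0315, a call lost with DESeq2, with no filter and without any 1 of 5 single libraries) and Ifngr2 one of 0.09 (edgeR adjusted p = 0.376). Cxcl9 stood near 1 CPM in both groups and Cxcl10 at 4.95 and 7.87 CPM (edgeR adjusted p = 0.717 and 0.124). Without IFN-γ replicate 2, Cxcl10 had a log2 fold change of 1.09 with an edgeR adjusted p of 0.0133, and with the replicate block it had one of 0.67 with an edgeR adjusted p of 0.0484.

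Genes stimulated by type I interferon fell in 23 of 27 cases and none rose, with a median of -1.88 (camera adjusted p = 3.19e-11, and adjusted p = 0.173 with an estimated correlation). Adjusted over the list alone, 25 fell and 1 rose. Oas2 and Oas3, sensors of double-stranded RNA, fell 8.83-fold and 9.29-fold, Xaf1 5.52-fold and Zbp1 5.32-fold. Rtp4 fell from 17.9 ± 2.65 to 1.33 ± 0.496 CPM (log2 fold change -3.70 ± 0.23, SE; edgeR adjusted p = 1.26e-05). Markers of monocytes fell beside both interferon lists, in 6 of 9 cases with a median of -1.21.

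Of 15 genes of MHC class II presentation, 10 fell and none rose, with a median of -0.58 (camera adjusted p = 4.85e-04, and adjusted p = 0.388 with an estimated correlation). H2-DMa and H2-DMb2, whose products edit the peptides loaded on class II molecules, fell 2.68-fold and 3.20-fold, and H2-Ob fell 3.56-fold. H2-Ab1, a chain of the class II molecule itself, fell from 1305 ± 175 to 893 ± 69.8 CPM (edgeR adjusted p = 0.00780). Markers of conventional dendritic cells and of monocytes fell as well, with medians of -0.72 and -1.21. Class I presentation genes went both ways, with 4 of 21 higher and 7 lower (camera adjusted p = 0.731): Erap1 fell 1.91-fold, and H2-Q4 and H2-Q7 rose 1.90-fold and 2.86-fold, though class I genes are alike in sequence and reads they may share were not measured. Erap1 shares 14.6% of its exon bases with Cast on the opposite strand.

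Maturation and costimulation genes of dendritic cells fell in 16 of 25 cases and rose in 4, with a median of -0.46 (camera adjusted p = 0.0116, and adjusted p = 0.517 with an estimated correlation), beside the markers of conventional dendritic cells, with a median of -0.72, and of monocytes, with one of -1.21. Ccl17, a chemokine for T cells, fell from 523 ± 119 to 93.6 ± 12.4 CPM, Slamf1 fell 4.73-fold and Fscn1, an actin-bundling protein of mature dendritic cells, 2.61-fold. The costimulatory genes Cd80, Cd86 and Cd40 fell less, with log2 fold changes of -0.37, -0.56 and -0.46 (edgeR adjusted p = 0.00413, 0.00117 and 0.00852). Il12b, a subunit of interleukin 12, fell 1.44-fold (edgeR adjusted p = 9.59e-04). The 4 that rose were Birc3, Tnfsf9, Icam1 and Tnfsf4. Of 22 migration and adhesion genes, 14 fell and 3 rose, with a median of -0.58 (camera adjusted p = 0.00992, and adjusted p = 0.173 with an estimated correlation). Ccr2, a chemokine receptor of monocytes, fell from 124 ± 4.95 to 15.6 ± 1.15 CPM, while Mmp12, Icam1 and Ccr1 rose.

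Inflammatory cytokines and chemokines divided, with 9 of 27 higher and 12 lower (camera adjusted p = 0.875). The neutrophil-attracting chemokines Cxcl1, Cxcl2 and Cxcl3 rose 9.93-fold, 11.0-fold and 20.3-fold, Cxcl3 from 480.1 ± 90.1 to 9736 ± 1643 CPM. Tnf fell 2.09-fold (edgeR adjusted p = 1.16e-04). Il1b was 1.36-fold higher (edgeR adjusted p = 0.0307), a call lost with total-count scaling and without any 1 of the 3 libraries with 4-OI, and Il6 had a log2 fold change of 0.05 (edgeR adjusted p = 0.757), which became -0.13 (edgeR adjusted p = 0.0163) without IFN-γ replicate 1 and 4-OI replicate 3. NF-κB feedback genes were higher in 3 and lower in 10 of 22 cases (camera adjusted p = 0.258), Nfkb1 and Tnfaip3 falling 1.68-fold and 1.51-fold and Birc3 rising 1.59-fold. Inflammasome genes were higher in 6 and lower in 8 of 18 cases (camera adjusted p = 0.731), with Pycard, the adaptor ASC, and Mefv falling 2.45-fold and 1.97-fold and Ninj1 rising 2.19-fold.

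**Figure D2:**
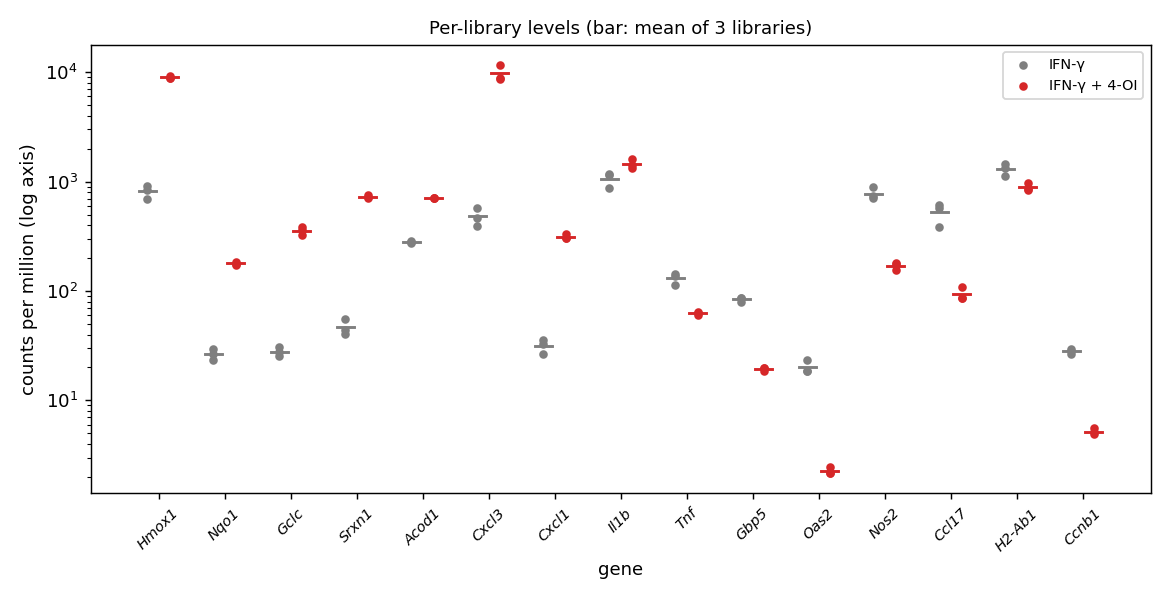
Normalised level of 15 genes (x axis) in CPM on a log axis (y axis); points are single libraries with IFN-γ (grey) or with IFN-γ and 4-OI (red), bars are means of 3 libraries. Hmox1 libraries lie near 8948 CPM with 4-OI and 813 without, and Oas2 libraries near 2.27 and 20.2.

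Proliferation genes fell in 23 of 26 cases and none rose, with a median of -2.03 (camera adjusted p = 4.44e-12, and adjusted p = 0.146 with an estimated correlation), beside markers of mast cells and basophils, with a median of -1.58, and of monocytes, with one of -1.21. The cyclin genes Ccna2 and Ccnb1 fell 4.89-fold and 5.38-fold and Cdc20 5.88-fold, and Pcna, Mcm2 and E2f1 did not pass. Cholesterol synthesis genes fell in 22 of 24 cases and none rose, with a median of -0.55 (camera adjusted p = 4.15e-06, and adjusted p = 0.173 with an estimated correlation). Acat2 and Stard4 fell 2.09-fold and 1.89-fold. Among 19 genes of lipid efflux and LXR targets, 4 were higher and 8 lower (camera adjusted p = 0.731). The scavenger receptor gene Cd36 rose from 51.0 ± 6.26 to 701 ± 25.9 CPM and Plin2, a coat protein of lipid droplets, 8.72-fold, while Pparg fell 3.79-fold.

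Lists of energy metabolism did not pass by camera. Of 22 glycolysis genes, 4 were higher and 6 lower (camera adjusted p = 0.737), with Pfkp, Pfkm and Hk1 lower by 2.03-fold, 1.65-fold and 1.54-fold. Of 22 genes of the citric acid cycle, 2 were higher and 5 lower (camera adjusted p = 0.848): Pcx, pyruvate carboxylase, and Ogdh rose 3.13-fold and 1.73-fold and Idh3a fell 1.64-fold. None of 24 oxidative phosphorylation genes passed by edgeR, DESeq2 or limma-voom, nor did any have an unadjusted p under 0.05 (camera adjusted p = 0.848), and Uqcrc2, with the smallest p, had a log2 fold change of -0.22 (edgeR adjusted p = 0.105). Without IFN-γ replicate 1 and 4-OI replicate 3, the libraries that stood apart, 15 of the 24 passed as lower, as did 3 without IFN-γ replicate 1 alone and 7 with total-count scaling. The libraries left without both also differed by group on the second component, at -19.1 and -16.8 with IFN-γ and 12.4 and 5.84 with 4-OI. That fit therefore cannot tell an effect of 4-OI from the spread on that component. Uqcrc2 shares 26.7% of its exon bases with Pdzd9 on the opposite strand.

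The remaining lists went both ways. Genes of the integrated stress response were higher in 13 and lower in 8 of 26 cases (camera adjusted p = 0.258), Slc3a2 rising 2.45-fold and Slc7a5 and Nupr1 falling 3.22-fold and 3.61-fold. Genes of the unfolded protein response were higher in 3 and lower in 2 of 20 (camera adjusted p = 0.731), with Dnajb9 up 1.53-fold, Derl3 up 3.10-fold from about 0.336 CPM and Xbp1 down 1.75-fold. Hypoxia genes were higher in 2, Hilpda and P4ha2, and lower in 8 of 20 (camera adjusted p = 0.200), with Arg1, arginase 1, falling 6.57-fold. Targets of p53 were higher in 6 and lower in 8 of 20 (camera adjusted p = 0.985), Gdf15 and Plk2 rising 13.5-fold and 2.52-fold and Perp falling 3.36-fold. Immediate early genes were higher in 2 and lower in 11 of 23 (camera adjusted p = 0.193), Jun rising 2.14-fold and Egr3 and Myc falling 5.79-fold and 5.40-fold. Lectin, scavenger and Fc receptor genes were higher in 8 and lower in 12 of 24 (camera adjusted p = 0.620), with Clec4d rising 3.63-fold and Clec4a3 falling 4.79-fold.

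Markers of several cell types that a GM-CSF culture can hold were lower with 4-OI. All 7 tested markers of mast cells and basophils fell, with a median of -1.58 (camera adjusted p = 4.84e-05, and adjusted p = 0.173 with an estimated correlation). Monocyte markers fell in 6 of 9 cases (camera adjusted p = 0.00167, and adjusted p = 0.173 with an estimated correlation), and 7 adjusted over the list alone. Neutrophil markers fell in 9 of 14 cases and rose in 2, Ly6g and S100a8, with a median of -0.60 (camera adjusted p = 0.00829, and adjusted p = 0.571 with an estimated correlation). Markers of conventional dendritic cells fell in 10 of 14 cases and 1, Clec9a, rose, with a median of -0.72 (camera adjusted p = 0.0150, and adjusted p = 0.173 with an estimated correlation). Macrophage markers were higher in 5 and lower in 4 of 15 (camera adjusted p = 0.731). Eosinophil markers were higher in 2 and lower in 4 of 7 (camera adjusted p = 0.200). Plasmacytoid dendritic cell markers were higher in 1 and lower in 1 of 4 (camera adjusted p = 0.737). T and NK cell markers were lower in 2 of 3 (camera adjusted p = 0.200) and stromal markers in 3 of 4 (camera adjusted p = 0.0553). The stromal list passed as lower with the replicate block (camera adjusted p = 0.0372) and without each single library (camera adjusted p = 0.00786 to 0.0317). None of 6 B cell markers passed by edgeR, DESeq2 or limma-voom, and none had an unadjusted p under 0.05 (camera adjusted p = 0.731), but Cd79b passed as lower without IFN-γ replicate 1 and without both libraries that stood apart, and Cd79b, Cd79a and Pax5 were among those that passed as lower with total-count scaling.

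The largest rises among named genes at 10 CPM or more were those of Adh7, Cxcl5, Shisa4, Ppbp, Gssos2, Rgs9bp, Cyp4a12a, Prdx1, Cxcl3 and Lypd6b. Adh7, an alcohol dehydrogenase, had 4 counts over the 3 IFN-γ libraries together and 850 with 4-OI, so the size of its rise is poorly bounded. Cxcl5 went from 2.24 ± 1.69 to 190.0 ± 28.6 CPM (log2 fold change 6.44 ± 0.43, SE; edgeR adjusted p = 1.63e-05) and Ppbp from 11.2 ± 7.43 to 767 ± 54.1 CPM (edgeR adjusted p = 2.37e-05), with wide spreads between IFN-γ libraries. Without single libraries their log2 fold changes were 6.05 to 7.23 for Cxcl5 and 5.84 to 6.82 for Ppbp, so the size of these rises is poorly bounded as well. They lie on chromosome 5 at 90907157 to 90909484 and at 90916377 to 90917922, beside Cxcl3 at 90933960 to 90935952. Shisa4 was 75.6-fold higher (log2 fold change 6.24, and 5.80 to 6.93 without single libraries), from 57 counts over the 3 IFN-γ libraries together, with the same limit. Cyp4a12a was 34.6-fold higher; it has a close relative, Cyp4a12b, and reads that both may share were not measured. Gssos2 was 39.4-fold higher; it shares 7.71% of its exon bases with Gss on the opposite strand, which was also higher. The largest falls were those of C1s1, Aldh1a2, Rtp4, Htra3, Cdh17, Klrb1f, Tespa1, Oas3, Slfn1 and Lipg. C1s1, a complement protease, fell from 25.7 ± 1.73 to 1.41 ± 0.333 CPM (log2 fold change -4.18 ± 0.16, SE; edgeR adjusted p = 2.17e-06) and Aldh1a2, which makes retinoic acid, from 15.2 ± 0.231 to 1.03 ± 0.187 CPM (edgeR adjusted p = 1.90e-06).

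Among the 34 lists tested, 14 passed by camera with a preset correlation, and none of the 14 passed with an estimated correlation, where the smallest adjusted p was 0.146. The counts of members rest on the test of each gene instead. All 14 were called in the same direction by fry, which does not compare a list with other genes. In other divisions of the 6 libraries into 3 and 3, the same camera test called between 5 and 17 lists. Each of those divisions mixed both groups and held part of the difference between them, so this range does not show what chance alone would call.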

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

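The fits without 2 libraries together and without the genes resembling ribosomal RNA were chosen after seeing the data. Leaving out those 2 libraries also set the groups apart on the second principal component, where they overlap with all libraries kept. Calls gained in that fit therefore cannot be told apart from that spread. The 4 counts stayed within 1.5 times of the reported ones in 67 of 69 recalculations; with total-count scaling 1719 genes were higher and 5452 lower, by the shift that scaling gives to all genes. Leaving out single libraries gave 5275 to 7835 changed genes, 2460 to 3791 higher, 2815 to 4044 lower and 2338 to 2576 changed at least 2-fold; without IFN-γ replicate 1 and 4-OI replicate 3 together it was 9296. No gene called in both settings turned direction under any alternative. With the replicate block, 7513 genes changed. Same-numbered libraries correlated by 0.26, -0.10 and 0.19 in their deviations from group means. Differently numbered libraries of unlike groups correlated by -0.34 to 0.31, a range that holds those values. Whether the numbers pair the libraries therefore cannot be decided from them. The block also gave the stromal markers an adjusted p of 0.0372 and Cxcl10 one of 0.0484, and called Keap1 no longer.

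With an estimated correlation the called lists gave adjusted p-values of 0.146 for proliferation, 0.173 for the NRF2, IFN-γ, type I interferon, heat shock, cholesterol and migration lists and for conventional dendritic cell, mast cell and monocyte markers, 0.251 for lysosome, 0.388 for MHC class II, 0.517 for maturation and 0.571 for neutrophil markers. By its construction that setting also takes its degrees of freedom from the libraries instead of the genes. For the migration list and conventional dendritic cell markers the estimated correlation was -0.017 and -0.032, below the preset 0.01. Their unadjusted camera p still rose, from 0.00350 to 0.0378 and from 0.00617 to 0.0509. For these lists that argues against correlation between members as the reason for the rise. Which part ended the adjusted calls was not otherwise tested. All 14 lists called by camera were called in the same direction by fry. fry, which does not compare a list with other genes, called 10 further lists: hypoxia (0.0109), immediate early (0.00470), NF-κB (0.00945), inflammasome (0.0117), eosinophil (0.00245), plasmacytoid (0.0227), T and NK cell (0.0237) and stromal (4.12e-04) as lower, and LXR (0.0369) and p53 (0.0109) as higher, against camera's direction. Stromal markers also passed with no filter (6.00e-04), at 1 CPM in 3 libraries (0.00993) and without single libraries (0.00786 to 0.0317). Without both libraries that stood apart, the hypoxia (0.0475), immediate early (0.0221), NF-κB (0.0312) and, reversed, oxidative phosphorylation (0.00663) lists passed as lower; the cause was not tested.

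Of 106 genes under the naming rule, 100 kept their call under every alternative that gave a value. Keap1 reversed to -0.0241 with total-count scaling, and Il6 to -0.13 without both libraries that stood apart, where it passed; the cause was not tested. Uqcrc2 passed with total-count scaling, without IFN-γ replicate 1 and without both libraries that stood apart; the calls lost for Keap1, Ifngr1 and Il1b and gained for Cxcl10 are given beside them in the results. Genes near 1 CPM are limited by depth.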

Other observations

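The patterns below were found in the same data that test them. The tests of abundant genes, monocytes and neutrophils and of the other divisions for the 4 gene counts were chosen after the values they use had been seen; the tests of the Cxcl5 region, platelets, GC content, PPAR targets and other divisions for gene lists were chosen before theirs.

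Beside Cxcl5, Ppbp and Cxcl3 on chromosome 5, genes chosen after their values were seen and which belong to other families were higher as well. Afp, alpha-fetoprotein, went from 1.37 ± 0.409 to 22.2 ± 1.43 CPM, and Ereg and Areg, which encode ligands of the EGF receptor, from 0.903 ± 0.317 to 8.82 ± 1.13 CPM and from 1.20 ± 0.123 to 8.32 ± 1.12 CPM (SD, n = 3). The edgeR adjusted p was 3.13e-06, 2.01e-05 and 8.52e-06.

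Cxcl5, Ppbp and Cxcl3 were higher in every library with 4-OI than in any with IFN-γ alone, which the rule for naming genes requires. Platelets or megakaryocytes in the cultures would raise their other genes as well. Of 8 of these, 3 rose, Itgb3, Pf4 and Clec1b, with log2 fold changes of 2.79, 1.36 and 1.28, 3 fell, Gp6, Nrgn and Itga2b, with -1.87, -1.34 and -0.71, and 2 did not pass. Their median was 0.12 (95% bootstrap interval -1.34 to 1.36), below the 4.34 of Cxcl3, the smallest rise of the 3 chemokines, which argues against platelets as the whole cause and leaves a smaller part open. The 14 neutrophil markers had a median of -0.60 (-1.24 to -0.28). The 7 tested genes within 500 kb that are not chemokines had a median of 2.79 (1.73 to 3.29), and 6 of them passed as higher. A candidate explanation is a rise shared by the region, although Ankrd17 at its edge had a log2 fold change of -0.07, and the mechanism was not tested. The 6 rises were unequal, from 1.73 for Mthfd2l to 4.02 for Afp. Chemokine genes were left out of that median, so it does not show whether every gene of the region rose.

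The type I interferon list fell with a median of -1.88. Abundant genes taking a larger share of the counts would shift all genes alike, yet the list median lay -1.87 from that of all genes, a difference that the choice of scaling does not change (95% bootstrap interval -2.40 to -1.08). A smooth trend of log2 fold change on GC content and length held 1.08% of its variance over tested genes and was nowhere lower than -0.38, so it is too small for that fall; with it removed the list median was -1.84. The list median lay -0.66 from that of the monocyte markers, with a 95% bootstrap interval of -1.79 to 0.24, drawn over genes and not over libraries. Fewer monocytes and lower interferon signalling cannot be told apart by this difference, because either could lower both sets of genes by unequal amounts.

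Pdk4 and the Cyp4a12 genes, chosen after their values were seen, rose from low levels, Pdk4 from 0.0773 ± 0.00865 to 4.05 ± 0.482 CPM and Cyp4a12b from 0.253 ± 0.152 to 9.41 ± 0.735 CPM. The nuclear receptor PPAR is known to raise Pdk4 in liver. Of 20 other PPAR targets 13 rose and 2, Acsl1 and Hadhb, fell, with a median log2 fold change of 0.70. As a list they had a camera adjusted p of 4.43e-05 together with the 34 lists. With an estimated correlation the camera adjusted p was 0.162, so the list did not pass there, as the other lists did not. The unadjusted camera p was 1.02e-05 and 0.0436. Activation of PPAR may contribute, as a hypothesis only, and Pparg, which encodes a PPAR, itself fell 3.79-fold. Cd36 and Plin2, with the largest log2 fold changes of the 20 at 3.78 and 3.12, are also in the LXR list, which was tested earlier. The PPAR list may therefore not have been chosen blind to their values. Camera called many lists in other divisions of these libraries, although those divisions hold part of the difference between groups.

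Of the 10 ways to divide the 6 libraries into 3 and 3, 1, the real one, gave 6736 changed genes, 3181 higher, 3555 lower and 2447 changed at least 2-fold, and the highest of the others gave 0 by edgeR, with 19 to 877 genes at an unadjusted p under 0.05. With 10 divisions no share under 0.05 can be reached. Each of the other divisions also mixed both groups. The difference between groups thus widened the spread within each side, and part of it remained between the sides. Their counts of genes and lists therefore do not show what chance alone would give. For gene lists and marker lists together, 4 of the 10 gave at least the real 14 lists, and the highest of the others gave 17.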
